A study of Mus musculus with 20 samples.

How the data were processed

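ATAC-seq had been done on Lin-cKit+Sca1+ (LSK) cells sorted from mouse bone marrow, with 20 libraries from 5 genotypes. The authors deposited one table of counts per peak for all libraries and one table that annotates the same peaks. Per the submitters' processing notes, Trim Galore, BWA, Picard, SAMtools, MACS2 and featureCounts were used and the genome build was mm10. Their order, versions and settings, and whether reads were shifted to the transposase position, are not given in the sources used here. The counts are whole numbers, as deposited, per peak of one peak set common to all libraries. Whether a count stands for a read or a fragment is not given in the sources used here. The table held 125343 peaks with a median width of 514 bp (157 to 4180 bp), and the annotation matched each by identifier. Coordinates are those of the deposited annotation, mm10, counted from 1.

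Each count column was tied to a sample by genotype and replicate number. For the 4 columns whose name joins the Idh1 gene with the R140Q change, the sample is Idh2 R140Q, since only that genotype carries the change. The annotation gives a class per peak (12.5% promoter, 41.9% intron, 36.0% intergenic, 5.5% exon, 4.2% transcription end), a distance to the nearest start site and Ensembl gene identifiers without symbols. The design had assumed symbols there. Gene names were therefore taken from the coordinates of 21900 protein-coding RefSeq genes of GRCm38.p6, the assembly that mm10 represents. A peak took the gene its centre lay in (the shortest where genes overlapped), otherwise the gene with the nearest boundary. Peak centres lay inside the named gene for 56.3% of peaks, and 17798 genes were named. A gene name thus marks a neighbour and not a regulated gene. Of the peaks in the promoter class, 61.4% lay within 1 kb of a RefSeq gene boundary, against 6.2% of the other peaks.

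Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the edgeR expression filter by genotype, and a robust quasi-likelihood fit with one mean per genotype over the 20 libraries. The filter removed 1435 peaks and left 123908. The common biological coefficient of variation was 7.73%. Adjusted p values are Benjamini-Hochberg values of the edgeR quasi-likelihood test over all tested peaks of a comparison, 2-sided, with a threshold of 0.05. Levels are CPM values (counts per 1e6) with TMM-scaled library sizes, given as mean ± SD over 4 libraries. Log2 fold changes come from the fit. Tests, contrasts, gene lists and most alternatives were fixed before the data were examined. Those added later are named in the closing section.

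Named genes followed a fixed rule. In each comparison with WT it took the first 10 raised and first 10 lowered genes by p among called peaks where every mutant library lay beyond every WT library, predicted gene models left out. It also took up to 3 genes by p with a called peak from each gene list, and all peaks of Tet2, Idh1, Idh2 and Vav1. Between mutants, the first 5 in each direction were taken. The 19 gene lists were HSC, megakaryocyte, erythroid, heme synthesis, myeloid, mast cell with basophil and eosinophil, lymphoid priming, B cell, T and NK cell, dendritic cell with MHC class II, stroma and endothelium, interferon response, NF-kB and inflammatory, immediate early, cell cycle, HoxA and partners, 2-oxoglutarate dioxygenases, hypoxia targets and p53 targets. Lists of mature blood cells and stroma also served as markers of other cells that the gate could hold. All tested peaks named for a member entered camera (limma 3.58.1, on voom values) with a preset correlation of 0.01, adjusted over the 76 tests of 19 lists and 4 comparisons. It was repeated with an estimated correlation. The fry test asks whether the peaks of a list move on balance in one direction, and its mixed p whether they change in either direction. Neither compares the list with other peaks.

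Fold changes of genotype pairs were compared by Pearson correlation and covariance across peaks, which are not independent replicates. Because the pairs share the WT libraries, 100 data sets with unchanged groups were simulated, and the WT libraries were also split so that a pair shared no control. Promoter shares and calls near the targeted genes were tested with Fisher's exact test, 2-sided, over peaks as units. The edgeR step was tested on simulated data with known changes in 122616 peaks. For Idh1 R132H it recovered 76% of 2-fold and 91.8% of 3-fold changes, for Idh2 R140Q 70% and 93.9%, for Idh2 R172K 65.3% and 85.7%, and for Tet2 knockout 68% and 88%. Changes of 1.25-fold were recovered in 8%, 6.12%, 12.2% and 14% of cases in the same order, so small changes were mostly below detection where few peaks change. The simulation changed 49 or 50 peaks per fold size and genotype. False calls made up 12 of 124 simulated calls for Idh1 R132H and 9 of 116 for Idh2 R140Q. They made up 7 of 101 for Idh2 R172K and 12 of 113 for Tet2 knockout. Each of these shares lay above the adjusted p threshold. In the data 53% of peaks were called in Idh2 R172K, which makes the adjusted cutoff less strict. These recoveries and false calls therefore do not describe that comparison. PCR copies are not independent molecules, so counting precision is an upper limit.

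Replicate pairs differed by a chi-square per peak of 1.15 (Tet2 knockout replicates 3 and 4) to 3.03. The next lowest value was 1.44 (Idh2 R172K replicates 2 and 3), so Tet2 knockout replicates 3 and 4 lay nearest to sampling noise. The labels name them as separate pools, and all 20 libraries were kept. Since the counts do not settle whether these 2 are independent, they were also summed as 1 library in an alternative. Whether equal replicate numbers pair libraries was checked by correlating deviations from the genotype means. Each same-number correlation exceeded 0.1 for Idh1 R132H with WT (0.102 to 0.232) and for Idh2 R140Q with WT (0.115 to 0.275). The other 5 pairs checked failed that rule, for example Idh2 R172K with WT (-0.0479 to 0.122). Failing it does not mean that numbers had no effect. In Idh1 R132H with Idh2 R172K (0.0556 to 0.178) all 8 libraries correlated best with their own number. In Tet2 knockout with WT 3 libraries did. The labels give no meaning to the numbers. They state that each pool is a biological replicate, and give no sex, sequencing date or batch.

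Alternatives were other scalings, filters, tests (DESeq2 1.42.0 and limma voom with quality weights), thinned counts, a replicate block, fewer samples, left-out replicates and the signal at Xist as a covariate or a split. Motif tests and corrections for GC content needed a genome sequence, which was not used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Some peaks that the naming rule selects are not reported here.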

Results

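Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The cells were LSK cells, the bone marrow compartment that holds mouse stem cells and multipotent progenitors. Each of the 5 genotypes had 4 libraries, and every library joined 2 animals aged 3 to 4 months. WT controls carried Vav-Cre, a recombinase expressed in blood cells, and no mutation. The Idh genotypes carried Vav-Cre with 1 Cre-activated mutant allele: Idh1 R132H, Idh2 R140Q or Idh2 R172K, changes that make the enzyme produce 2-hydroxyglutarate. The Tet2 knockout mice lacked Tet2, an enzyme that oxidizes 5-methylcytosine, and their label names no Cre. Counts in peaks per library ran from 14.51 to 26 M (M for 1e6) in WT, 17.44 to 27.89 M in Idh1 R132H, 16.76 to 27.74 M in Idh2 R140Q, 10.5 to 27.81 M in Idh2 R172K and 21 to 25.63 M in Tet2 knockout.

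The libraries parted mainly by the Idh2 R172K genotype. On the first principal component, with 49.6% of the variance, the 4 Idh2 R172K libraries scored 176.7 to 199.9 and the other 16 scored -77.2 to -16.2. Promoter-class peaks took 43.3% to 44.4% of the counts in Idh2 R172K libraries and 40.6% to 43.1% in the others. The 4 peaks at Xist, the RNA that silences an X chromosome in female cells, split the libraries into a low set (3.91 to 5.17 CPM) and a high set (32.2 to 40.4 CPM). Replicates 2 and 4 were high in WT and the 3 Idh genotypes, and replicates 3 and 4 in Tet2 knockout. Y-linked peaks had signal in every library (mean 233 ± 57.8 CPM in WT, 153 ± 8.22 in Idh1 R132H, 218 ± 56.4 in Idh2 R140Q, 182 ± 20.6 in Idh2 R172K and 278 ± 16.7 in Tet2 knockout, SD, n = 4 each). Y signal did not part the sets. In WT the Xist-high libraries had 244 and 302 CPM and the low ones 222 and 162. In Idh2 R172K the high ones had 178 and 157 CPM and the low ones 207 and 188. The sets are therefore not shown to be female and male. Since mouse sex is not in the labels, comparisons were also made within the low and the high libraries.

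**Figure D1:**
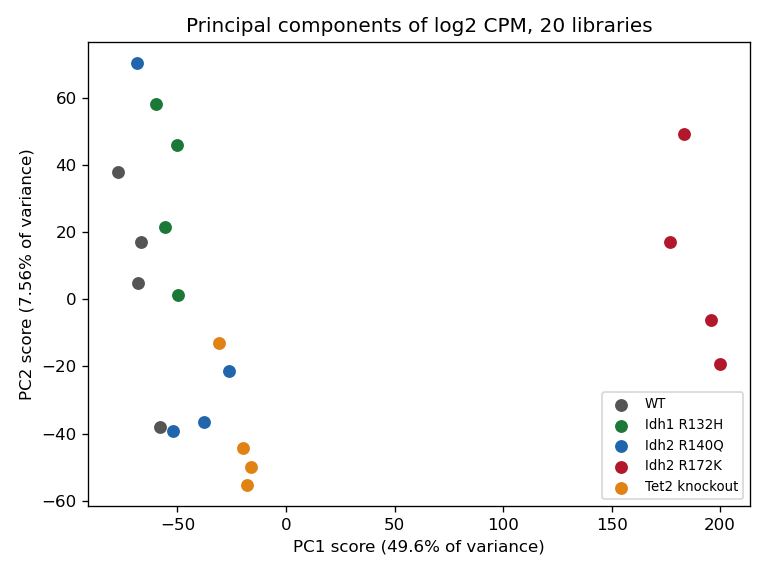
Scores of the 20 libraries on the first (x axis, 49.6% of variance) and second principal component (y axis, 7.56%) of log2 CPM, 1 point per library, coloured by genotype. The 4 Idh2 R172K libraries stood alone at 176.7 to 199.9 on the first component.

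Peaks of the targeted genes were examined first. Tet2 had 30 peaks on chromosome 3 and none was called in Tet2 knockout by edgeR (lowest adjusted p = 0.101): the promoter peak at 133544011 to 133545353 held 50 ± 4.03 CPM in WT and 51.6 ± 2.42 in Tet2 knockout (SD, n = 4 each). The labels do not say which part of Tet2 was deleted, and peaks outside that part cannot check the label. Idh2 had 8 peaks on chromosome 7. In Idh2 R172K 7 of them were raised, such as the one at 80114288 to 80115707 in an intron, which rose from 50.2 ± 2.59 to 87.8 ± 1.89 CPM (log2 fold change 0.81, adjusted p = 1.69e-15), and in Idh2 R140Q none was called (lowest adjusted p = 0.917). Idh1 had 2 peaks on chromosome 1, neither called in Idh1 R132H (lowest adjusted p = 1) and both raised in Idh2 R172K. The call at 65178060 to 65179449 was lost with cyclic loess scaling, where the Idh1 log2 fold change went from 0.25 to 0.06 (adjusted p = 0.327). Vav1, whose regulatory DNA drives Vav-Cre, had 12 peaks on chromosome 17. Of these 3 were lowered in Tet2 knockout, and none was called in Idh1 R132H or Idh2 R140Q (lowest adjusted p = 1 and 0.959). The intronic Vav1 peak at 57290002 to 57291273 fell from 165 ± 1.07 CPM in WT to 65.1 ± 4.79 in Tet2 knockout (log2 fold change -1.34, adjusted p = 2.45e-20) and held 159 ± 5.09 to 177 ± 6.01 in the Idh genotypes. The Vav1 promoter peak at 57278748 to 57279507 (log2 fold change -0.70) and the peak upstream at 57276643 to 57277164 (-0.71) fell as well, each with adjusted p = 2.21e-09. At the upstream peak Idh2 R172K was also lower than WT (-0.37, adjusted p = 1.08e-05).

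**Figure D2:**
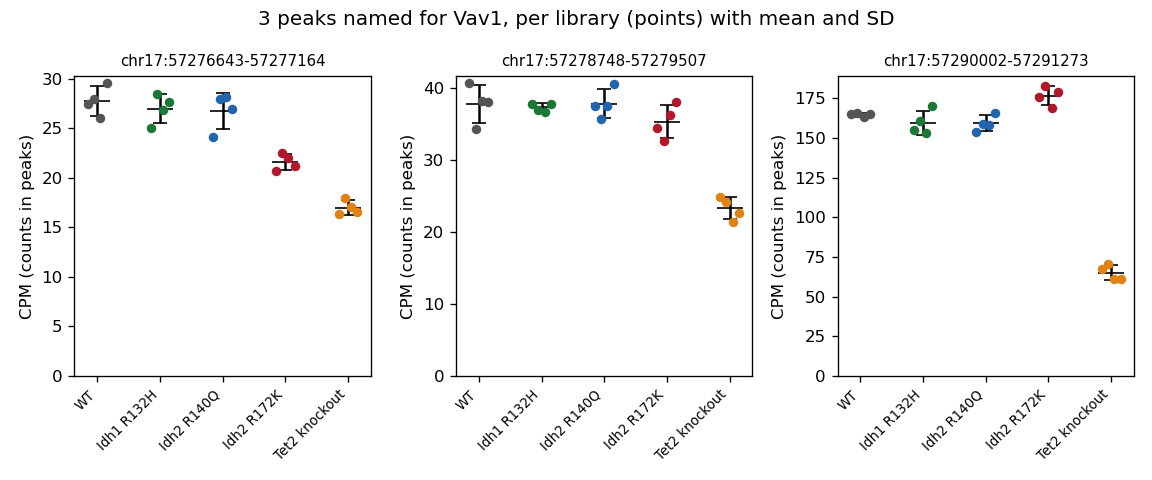
CPM per library (points) with mean and SD (bars, n = 4) at the 3 Vav1 peaks on chromosome 17 that were lowered in Tet2 knockout, with genotypes on the x axis and CPM from 0 on the y axis. At 57290002 to 57291273 Tet2 knockout averaged 65.1 CPM and WT 165 CPM.

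Idh2 R172K changed accessibility at 65673 of the 123908 tested peaks (53%), 31075 raised and 34598 lowered. The balance depended on the scaling, with 32279 raised and 31350 lowered by cyclic loess and 23277 and 38486 by library size. A peak in an intron of Mmp15, a membrane-bound matrix metalloproteinase, at 95369425 to 95370383 on chromosome 8 fell from 18.1 ± 1.67 to 0.719 ± 0.12 CPM (SD, n = 4 each; log2 fold change -4.70, adjusted p = 3.96e-26). Peaks of Dhx15 (-3.40), Rab3ip (-3.79), Fnbp1 (-2.91) and Col5a1 (-3.61) fell as well. An intronic peak of Sgcd, a sarcoglycan, at 47777135 to 47777848 on chromosome 11 rose from 0.639 ± 0.149 to 9.20 ± 2.50 CPM (3.85, adjusted p = 7.78e-19), and the promoter-class peak of Sema4b on chromosome 7 rose from 35.9 ± 1.87 to 79.2 ± 4.91 CPM (1.14). Raised peaks included Arhgap45 (2.52), Arap1 (2.06), Ap3b1 (1.68) and Tmem17 (1.68). Changes beyond 2-fold were more often losses, with 16403 lowered and 4504 raised, and the median size of a called change was 0.715 on the log2 scale. Within the libraries low at Xist 52385 peaks were called and within the high ones 42975.

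Where the Idh2 R172K changes lay was set against peaks not called, with Fisher's exact test over peaks, which are not independent. Promoters made up 20% of raised peaks against 12.1% of peaks not called (odds ratio 1.82, 95% interval 1.75 to 1.89) and 6.77% of lowered peaks (odds ratio 0.529, 0.504 to 0.556). With cyclic loess scaling, which removes trends with peak strength, the promoter share of raised peaks turned to a deficit (odds ratio 0.737), and lowered peaks stayed poor in promoters (0.588). Among promoter peaks 39.8% were raised and 15% lowered, among intron peaks 22.6% and 30.8%, and among intergenic peaks 22.1% and 30.1%.

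Members of the blood lists moved both ways in Idh2 R172K. Of 354 HSC peaks 87 rose and 108 fell (88 and 111 adjusted over the list alone). A peak near Gata2, a transcription factor that stem cells need, at 88165878 to 88166641 on chromosome 6 fell from 11.6 ± 0.816 to 1.35 ± 0.315 CPM (log2 fold change -3.09, adjusted p = 1.86e-20), and peaks of Prdm16 (-3.24) and Angpt1 (-2.85) fell with it. Of 165 megakaryocyte peaks 47 rose and 43 fell (47 and 43 adjusted over the list alone), and the promoter-class peak of Itga2b, the integrin alpha IIb chain of platelets, rose from 31.9 ± 1.81 to 48.7 ± 2.74 CPM (0.61), while Cd9 fell (-1.60). The erythroid list had 54 raised and 80 lowered of 217 peaks, the same numbers adjusted over the list alone, with Zfpm1, a cofactor of GATA factors, at -2.32 and Ank1 at -1.76. Heme synthesis had 15 and 13 of 39, again the same over the list alone, with Alad (-3.21), Alas1 (-2.09) and Cpox (-1.71) lowered. In the myeloid list 49 rose and 92 fell of 258 (49 and 92 adjusted over the list alone), where Csf3r, the G-CSF receptor, was raised (1.00), as was Ly86 (0.72), and Fcer1g was lowered (-1.15). The mast cell, basophil and eosinophil list had 15 and 15 of 56, unchanged over the list alone, with Cpa3, a mast cell protease, at 3.04 and Hdc, which makes histamine, at -1.06.

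Lymphoid and antigen-presenting lists had more lowered than raised peaks in Idh2 R172K, as had the HSC, erythroid and myeloid lists above. All tested peaks leaned the same way, with 31075 raised and 34598 lowered of 123908. Lymphoid priming had 36 raised and 70 lowered of 202 (36 and 69 adjusted over the list alone), among them Lsp1 (-2.81) and Dntt (-1.82), the terminal transferase of early lymphoid cells. The B cell list had 8 and 33 of 85 (8 and 29 adjusted over the list alone), with Pax5, the B cell commitment factor, at -3.28 and Pou2af1 at 2.40. The T and NK cell list had 28 and 47 of 152 (28 and 47 over the list alone), with Tcf7 at -2.58. The dendritic cell and MHC class II list had 43 and 81 of 212 (43 and 82), with Tcf4 at -2.86 and Batf3 at 1.13. Stroma and endothelium, cells the gate should exclude, had 45 and 48 of 155 (46 and 48).

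Signalling and metabolic lists held raised and lowered peaks as well. Interferon response had 22 raised and 20 lowered of 88 peaks (19 and 19 adjusted over the list alone), with Ifih1, an RNA sensor, at -3.49. NF-kB and inflammatory had 54 and 64 of 209 (54 and 64), with Nfkb1 at -2.25 and Il6 at 1.19. Immediate early had 90 and 108 of 341 (91 and 109), with Myc at -1.73. Cell cycle had 24 and 23 of 108 (21 and 21), with Aurkb at -1.39. HoxA and partners had 43 and 17 of 115 (43 and 17), with Meis1 at 1.55 and Hoxa3 at -1.82. The 2-oxoglutarate dioxygenases, the enzyme class that 2-hydroxyglutarate can inhibit, had 75 and 73 of 271 (76 and 73), with Fto at -2.05 and Kdm3b at 1.33. Hypoxia targets had 41 and 40 of 146 (41 and 40), with Vegfa at -2.08. For p53 targets 33 and 25 of 96 were called (33 and 25), with Plk2 at -2.82 and Bbc3 at 0.46. None of the 19 lists stood apart from other peaks in camera (smallest adjusted p = 0.215, HoxA and partners, then 0.281, B cell), although 2 passed an unadjusted p of 0.05 and fry moved 9 on balance, megakaryocyte and HoxA upward and 7 downward. Median and mean log2 fold change differed in sign for HSC (0.01 and -0.22), megakaryocyte (0.06 and -0.05), heme synthesis (0.10 and -0.36), mast cell (-0.08 and 0.06), interferon, NF-kB, cell cycle, 2-oxoglutarate dioxygenases and p53 targets, and for hypoxia targets the camera direction was up while both were negative.

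**Figure D3:**
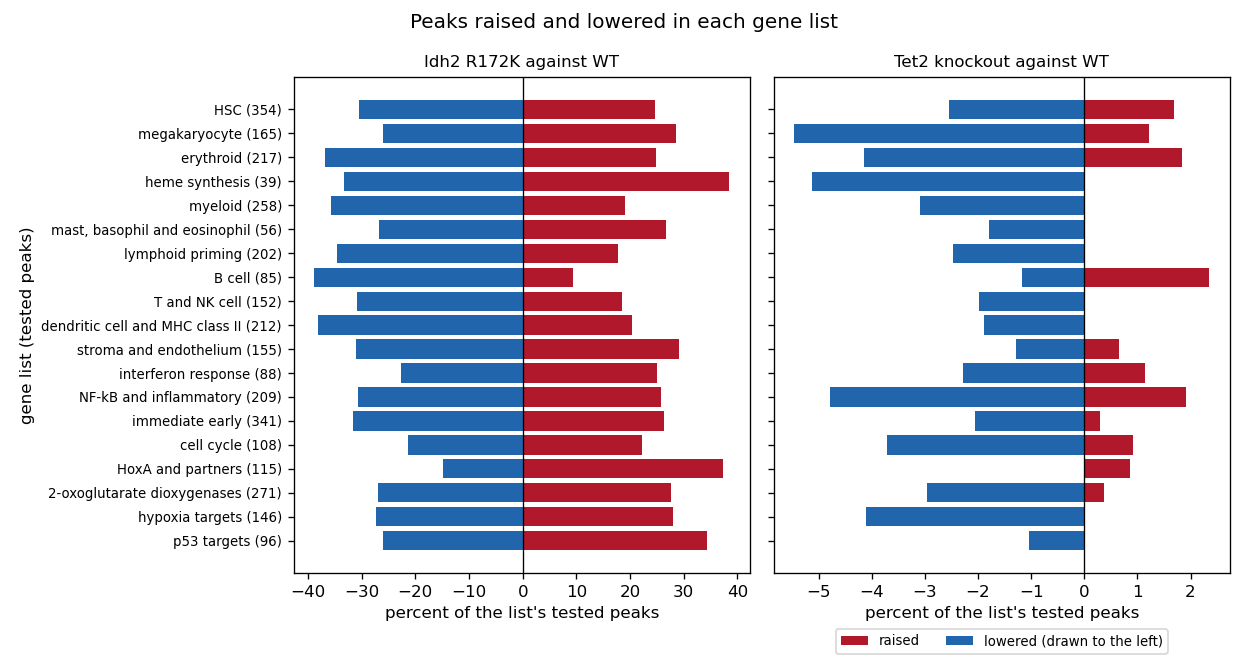
Percent of each gene list's tested peaks (number in brackets) called raised (right) and lowered (left) in Idh2 R172K and in Tet2 knockout against WT, on x axes of different scale. HSC had 87 raised and 108 lowered of 354 peaks in Idh2 R172K, and 6 and 9 in Tet2 knockout.

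Tet2 knockout changed 3844 peaks (3.1%), 973 raised and 2871 lowered. Besides Vav1, an intronic peak of Arhgef4, a guanine nucleotide exchange factor, at 34677578 to 34679052 on chromosome 1 fell from 12.9 ± 0.433 to 5.03 ± 0.64 CPM (SD, n = 4 each; log2 fold change -1.35, adjusted p = 1.89e-12). Lowered peaks lay inside Atrnl1 (-1.72), Sh3rf1 (-1.79), Fyb (-0.82) and Drosha (-1.69), a microRNA-processing enzyme, and near Jarid2 (-1.17), a partner of Polycomb repressive complex 2, Npc2 (-1.51) and Sall1 (-1.03). Raised peaks included Pmepa1 (0.79), which went from 4.16 ± 0.478 to 7.27 ± 0.468 CPM (adjusted p = 6.88e-06), Pias4 (0.72), Gli2 (1.20), a Hedgehog pathway factor, Chst8 (1.69) and Tead3 (0.57). Beyond 2-fold 845 peaks were lowered and 115 raised. Promoters made up 5.82% of lowered peaks against 12.7% of peaks not called (Fisher's exact test, odds ratio 0.424, 95% interval 0.36 to 0.496), and 13.1% of raised ones (1.03, adjusted p = 0.841). Chromosome 3, which carries Tet2, held 6.04% of the calls and 5.05% of tested peaks (Fisher's exact test, odds ratio 1.22, adjusted p = 0.00896). Within the Xist-low libraries 3635 peaks were called with 2279 raised, and within the Xist-high ones 2727 with 469 raised, so the balance of gains and losses differed between the sets. Leaving out 1 library gave 2370 calls (WT replicate 1), 2281 (WT replicate 2), 2485 (Tet2 knockout replicate 1) or 2116 (Tet2 knockout replicate 3).

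The myeloid list was the one list past the threshold in camera in Tet2 knockout (down, adjusted p = 0.00194), a call lost with adjusted p = 0.561 with an estimated correlation (range over the alternatives 0.000179 to 0.561). Of its 258 peaks 0 rose and 8 fell (0 and 11 adjusted over the list alone), with a median log2 fold change of -0.10. Peaks near Irf8, a factor of monocytes and dendritic cells (-1.28), Mpo, the granule enzyme myeloperoxidase (-0.68), and F13a1 (-0.58) fell, F13a1 from 7.71 ± 0.398 to 5.17 ± 0.407 CPM (adjusted p = 0.000655). HSC had 6 raised and 9 lowered of 354 (6 and 10 adjusted over the list alone): Gata2 fell (-0.83) at the peak that fell in Idh2 R172K, and Slamf1 fell (-0.89). Megakaryocyte had 2 and 9 of 165 (2 and 10), with Cd9 at -0.54, erythroid 4 and 9 of 217 (7 and 15), with Zfpm1 at -1.06, and heme synthesis 0 and 2 of 39 (0 and 3), Fech (-1.33) and Alas1 (-0.36). Mast cell, basophil and eosinophil had 0 and 1 of 56 (0 and 2), a peak of Hdc (-0.78) whose call was lost in 11 of 12 other settings. Lymphoid priming had 0 and 5 of 202 (0 and 5), with Ikzf1, the factor Ikaros, at -1.23.

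For B cell 2 rose and 1 fell of 85 (2 and 1 adjusted over the list alone), for T and NK cell 0 and 3 of 152 (0 and 3), for dendritic cell and MHC class II 0 and 4 of 212 (0 and 4), with Runx2 at -1.10, and for stroma and endothelium 1 and 2 of 155 (1 and 2), with Pdgfrb at 0.42. Interferon response had 1 and 2 of 88 (3 and 3 adjusted over the list alone) and NF-kB and inflammatory 4 and 10 of 209 (5 and 17), where Socs3 (-0.80), a brake on cytokine signalling, and Nfkbia (-0.54) fell and Tlr4 rose (0.51). Immediate early had 1 and 7 of 341 (1 and 6), with Fos (-0.76), Jun (-0.78) and Klf6 (-0.80), cell cycle 1 and 4 of 108 (1 and 4), with Mki67 at -1.36, and HoxA and partners 1 and 0 of 115 (0 and 0), the peak of Pbx3 (0.50), a call lost in 8 of 12 other settings. The 2-oxoglutarate dioxygenases had 1 and 8 of 271 (1 and 8), with Kdm7a at -1.29, hypoxia targets 0 and 6 of 146 (0 and 13), with Vegfa, the vascular growth factor, at -1.77, and p53 targets 0 and 1 of 96 (0 and 1), a peak near Plk2 (-1.01). These 18 lists gave camera adjusted p values of 0.109 (heme synthesis) to 0.927 (T and NK cell), and fry moved megakaryocyte, myeloid, mast cell, hypoxia and p53 lists downward and stroma upward. Median and mean differed in sign for T and NK cell and for the 2-oxoglutarate dioxygenases.

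The title of the series sets Idh and Tet2 mutations against each other, and the overlap of Idh2 R172K and Tet2 knockout was counted peak by peak. Of the peaks called in both 96.1% went the same way: 636 were raised in both (244 for independent lists), 2575 were lowered in both (802) and 129 were called in opposite directions. The numbers for independent lists ignore that both comparisons used the same WT libraries. Sall1 fell to 1.62 ± 0.148 CPM in Idh2 R172K and 6.25 ± 0.93 in Tet2 knockout, from 12.7 ± 1.48 in WT (SD, n = 4 each), and Ntrk2, Jarid2, Npc2 and Drosha had the same order. Fold changes correlated across peaks at r = 0.535, where unchanged groups sharing the WT libraries gave 0.485 in simulation. That simulated r holds for groups with no change, so it is no benchmark for the r of 2 changed genotypes. The covariance was 0.107 against 0.0193 simulated, and with WT libraries split so that none was shared r was 0.389. Tested directly, 54872 peaks differed between Idh2 R172K and Tet2 knockout, among them 1909 of the 3211 changed in the same direction. The 3211 became 2057 without WT replicate 1 and 1927 without WT replicate 2.

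Idh2 R140Q differed from WT at 19 peaks, 10 raised and 9 lowered, and 16 of them lay on chromosome 7, which carries Idh2 and 5.89% of tested peaks (Fisher's exact test, odds ratio 85.4, p = 1.69e-17). These 16 calls ran from 63.5 to 81.7 Mb, with Idh2 at 80.1 Mb. Within 10 Mb of Idh2 lay 8 of the 19 calls and 0.816% of tested peaks (odds ratio 89.1). A peak 36783 bp from Otud7a, a deubiquitinase gene, at 63802730 to 63803300 rose from 0.37 ± 0.131 to 11.5 ± 1.20 CPM (SD, n = 4 each; log2 fold change 4.99, adjusted p = 1.72e-22), and one near Fam169b rose from 0.168 ± 0.155 to 2.59 ± 0.415 CPM (4.12). Arrdc4 (2.44), Abhd2 (1.32), Ttc23 (0.87) and Hapln3 (0.58) were also raised, and Akap13 (-0.89), Homer2 (-1.38), Chsy1 (-0.45), Rlbp1 (-0.87, lost in 5 of 12 other settings) and another Otud7a peak (-0.69) were lowered. Of the 16 peaks 13 were called in the same direction in Idh2 R172K, with Otud7a at 4.34 and Fam169b at 3.51. Ttc23 went the other way there (-0.97), and Arrdc4 (0.86, adjusted p = 0.0661) and Abhd2 (-0.30, 0.294) were not called. The 3 lowered peaks elsewhere, Rab3gap2 (-0.58), Slc38a6 (-0.77) and Rap1gap2 (-0.69), were also called lowered in Idh2 R172K and Tet2 knockout, against the same WT libraries, and the sharing expected with no effect was not computed. Each of them lost its call in 5 or more of 12 other settings. Adjusted over the other chromosomes alone, 0 peaks passed in edgeR, where 6327 of 116608 (5.43%) had an unadjusted p under 0.05, while over all peaks DESeq2 called 2 there, limma voom 6 and edgeR with the replicate block 14. None of the lists was past the threshold in camera (1 at an unadjusted p of 0.05, 0 in fry): 0 peaks of the 19 lists were called over all peaks, and 1 lowered B cell peak adjusted over the list alone. The lowest camera adjusted p was 0.0745, for myeloid (down), which passed with the mean per gene (adjusted p = 0.00309) and without WT replicate 3, WT replicate 4, Idh2 R140Q replicate 1 or Idh2 R140Q replicate 2, and had adjusted p = 0.603 with an estimated correlation. With the replicate number as a block, 36 peaks were called. The Xist-low libraries gave 50 calls (42 raised, 8 lowered) and the Xist-high ones 17 (10 and 7), and there were 12 without WT replicate 1, 94 (13 raised, 81 lowered) without Idh2 R140Q replicate 2 and 33 without Idh2 R140Q replicate 3.

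**Figure D4:**
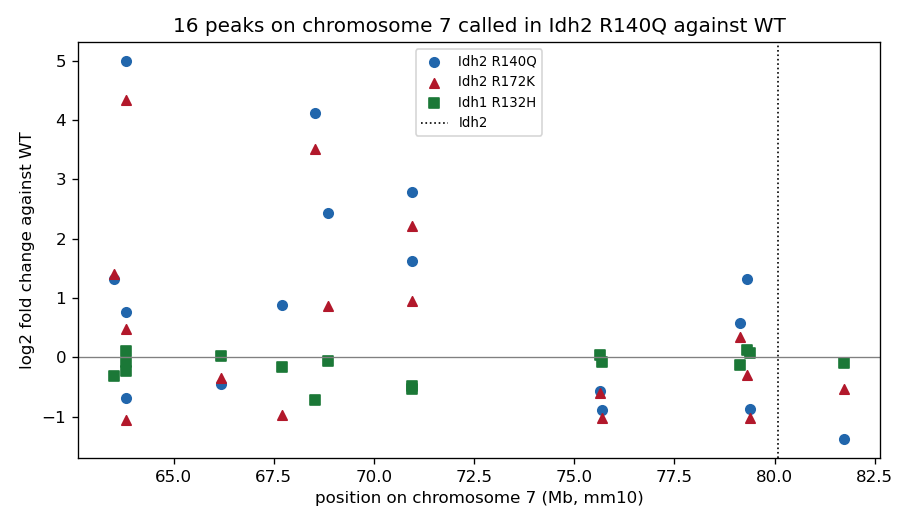
Log2 fold change against WT (y axis) at the 16 peaks on chromosome 7 that were called in Idh2 R140Q, by position in Mb (x axis, mm10), for Idh2 R140Q, Idh2 R172K and Idh1 R132H, with the dotted line at Idh2. The highest points, 4.99 in Idh2 R140Q and 4.34 in Idh2 R172K, are the Otud7a peak.

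Idh1 R132H differed from WT at 34 peaks, 8 raised and 26 lowered, 24 of them on chromosome 1, which carries Idh1 and 6.87% of tested peaks (Fisher's exact test, odds ratio 32.6, p = 7.95e-21). These 24 calls ran from 33.6 to 184.7 Mb, with Idh1 at 65.2 Mb. Within 10 Mb of Idh1 lay 8 of the 34 calls and 0.743% of tested peaks (odds ratio 41.3). A peak in Dst, the dystonin gene, at 33925330 to 33925745 rose from 0.341 ± 0.241 to 2.07 ± 0.741 CPM (SD, n = 4 each; log2 fold change 2.73, adjusted p = 2.55e-05), and Dnah7b (2.09), Slc40a1 (2.21, lost in 5 of 12 other settings), the iron exporter ferroportin, and Tsga10 (0.63) were raised. An intronic peak of Tns1, a focal adhesion protein, fell from 10.9 ± 1.03 to 6.62 ± 0.744 CPM (-0.72, adjusted p = 5.87e-05), and Lancl1 (-0.79), Cps1 (-1.32), Slc4a3 (-0.87) and Nck2 (-1.53) fell too. Of the 10 calls on other chromosomes 9 were called in the same direction in Idh2 R172K, among them Epb41l3 (-1.31 in Idh1 R132H and -1.34 in Idh2 R172K), and 1 in the opposite direction, Ifi27 (-0.57 in Idh2 R172K). Both comparisons used the same WT libraries, and the sharing expected with no effect was not computed. The promoters of Ifi27 (0.52), an interferon-induced gene on chromosome 12, and Med13l (0.39), on chromosome 5, were raised in Idh1 R132H, each with the call lost in 9 of 12 other settings. Adjusted over the other chromosomes alone 0 peaks passed in edgeR, where 5745 of 115392 (4.98%) had an unadjusted p under 0.05, while over all peaks DESeq2 called 11 there, limma voom 18, edgeR with the Xist covariate 23, with only the genotypes compared 61 and with the replicate block 62, of which 55 were called the same way in Idh2 R172K. Of the 19 lists, 1 mast cell peak (Il1rl1, -0.58) and 1 interferon peak (Ifih1, -1.02, lost in 9 of 12 settings) were lowered over all peaks. The Il1rl1 peak is among the 24 calls on chromosome 1. Its call was lost without WT replicate 1 or 2 and without Idh1 R132H replicate 3 or 4. Adjusted over the list alone, 3 mast cell, 1 interferon, 2 NF-kB and 1 dioxygenase peak were lowered. None of the lists passed the threshold in camera (adjusted p 0.357 to 0.929, 0 at an unadjusted p of 0.05) or in fry. The replicate block gave 96 calls. Xist-low libraries gave 34 calls with 19 raised, Xist-high ones 6, and there were 19 without WT replicate 1 and 18, 20 and 22 without Idh1 R132H replicates 1, 3 and 4.

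Between the Idh genotypes, Idh1 R132H and Idh2 R140Q differed at 51 peaks, 18 higher and 33 lower in Idh1 R132H, among them chromosome 1 and 7 peaks above: Dst (2.94) and Akap13 (0.81) were higher and Otud7a (-5.22), Fam169b (-4.83) and Tns1 (-0.89) lower in Idh1 R132H. With both chromosomes left out 0 peaks passed in edgeR, against 7949 at an unadjusted p under 0.05 over all peaks. Idh2 R172K differed from Idh1 R132H at 61930 peaks and from Idh2 R140Q at 58244. Relative to Idh2 R172K, Mmp15 was higher in Idh1 R132H (4.29) and Idh2 R140Q (4.49), Msl3l2 was higher by 2.87 and 2.90, and Ap3b1 was lower (-1.59 and -1.64). A peak 473180 bp from Nuf2 held 9.29 ± 1.00 CPM in Idh2 R172K and 0.454 ± 0.165 in Idh2 R140Q (SD, n = 4 each; -4.37, adjusted p = 1.99e-18). Xist-low and Xist-high libraries gave 61 and 21 calls for Idh1 R132H against Idh2 R140Q, 50735 and 37665 for Idh1 R132H against Idh2 R172K, and 47071 and 33972 for Idh2 R140Q against Idh2 R172K. Without Idh2 R140Q replicate 2 the first comparison had 570 calls, and the balance turned to 473 higher and 97 lower in Idh1 R132H.

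The mean of the 3 Idh genotypes differed from Tet2 knockout at 12783 peaks (10.3%), 3730 higher and 9053 lower in the Idh mean. At 672 of them (5.26%) the libraries of the Idh genotypes and of Tet2 knockout did not overlap, so a called peak need not differ in each Idh genotype. Vav1 (log2 difference 1.34, adjusted p = 9.82e-23) and Arhgef4 (1.26) were higher, as were the promoters of Tgfbr1, a TGF-beta receptor (123 ± 10.7, 122 ± 9.22 and 143 ± 9.44 CPM in Idh1 R132H, Idh2 R140Q and Idh2 R172K, 82 ± 5.89 in Tet2 knockout, SD, n = 4 each), and Tnpo3 (0.55). Mmp15 (-1.94), Noxa1 (-1.22), B4galt6 (-1.64) and Cenpo (-0.76) were lower, and there Idh2 R172K set the mean: Noxa1 held 2.38 ± 0.562 CPM in Idh2 R172K, 9.90 ± 1.07 in Idh1 R132H, 12 ± 0.767 in Idh2 R140Q and 15.4 ± 1.27 in Tet2 knockout. Xist-low libraries gave 9594 calls with 2411 higher, and Xist-high ones 11913 with 5790 higher. Without Tet2 knockout replicate 3 there were 8373.

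Fold changes of the other pairs of genotypes were set against the same kind of simulation. It gave libraries no effect of replicate number, although equal numbers correlated between WT and both Idh1 R132H and Idh2 R140Q. The simulated groups were unchanged, while log2 fold changes of Idh2 R172K had an SD of 0.782 across peaks (0.207 in Idh1 R132H). A wide spread in 1 genotype lowers r even where the covariance exceeds the simulated one. For pairs with Idh2 R172K an r below the simulated one therefore does not show less agreement than unchanged groups. Idh1 R132H and Idh2 R140Q correlated at r = 0.422 (0.5 simulated, -0.0364 with split controls, covariance 0.0164 against 0.0193 simulated), and Idh1 R132H and Tet2 knockout at 0.285 (0.512, -0.0377, 0.0154). Idh1 R132H and Idh2 R172K correlated at 0.295 (0.482 simulated), with a covariance of 0.0414 (0.0193 simulated) and r = 0.135 with split controls (0.0429 to 0.239 over the assignments). Idh2 R140Q and Idh2 R172K had r = 0.393 (0.474 simulated), covariance 0.0566 and 0.214 with split controls (0.152 to 0.28). Idh2 R140Q and Tet2 knockout had r = 0.545 (simulated range 0.493 to 0.515), covariance 0.0302 and 0.155 with split controls (0.093 to 0.23). That r was 0.436 without Idh2 R140Q replicate 4, 0.473 without replicate 1, and 0.494 and 0.421 in the Xist-low and Xist-high libraries. No peak was called in both Idh1 R132H and Idh2 R140Q by edgeR. Idh1 R132H shared 11 calls with Tet2 knockout (1 raised, 10 lowered, 0.0628 and 0.602 for independent lists), and Idh2 R140Q shared 4 lowered calls (0.209). The numbers for independent lists ignore the shared WT libraries, and no overlap of calls was simulated with shared controls.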

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

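The tests of promoter reads, cell types, chromosomes, alleles, Vav-Cre and Xist order below were chosen only after the result was seen, while that of cyclic loess scaling was set before. Among 50 groups of 4 libraries tested for a sample far from the others 4 had one, and among 142 groups of named peaks 4 had one, where chance gives about 1 in 20 groups (5%). WT replicate 3 had 14.51 M counts in peaks and the other WT libraries 24.23 to 26 M. Idh1 R132H replicate 2 had 67 peaks with no read, and its other libraries had 34 to 37. The TMM factor of Idh1 R132H replicate 4 was 0.973, and the others ranged from 1.006 to 1.012. Idh2 R140Q replicate 2 scored 70.2 on the second principal component, and the others -39.3 to -21.3. In WT replicate 3 the Myl1 peak had 16.3 CPM (18.2 to 18.6 in the others) and the Akap13 peak 11.2 (13 to 13.4). In WT replicate 2 the Dhx15 peak had 20.9 CPM (23.6 to 24) and the Sh3rf1 peak 4.21 (3.69 to 3.76).

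A difference between genotypes marked 129 peaks that were called in opposite directions in Idh2 R172K and Tet2 knockout, each also called in the direct test of the difference, which peaks picked for opposite calls against the same WT libraries pass almost by construction. Slc39a4 had log2 fold changes of -0.61 and 0.53, Noxa1 -2.16 and 0.50, Tns1 -2.34 and 0.76 and Ece1 0.65 and -0.58, in that order of genotypes.

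The first pattern weighed was the breadth of the Idh2 R172K change, 65673 peaks. A trend with peak strength left by the scaling was argued against, since 85% of the calls kept their direction and call with cyclic loess scaling. More reads in promoters as the whole cause were argued against by the 22.1% of intergenic peaks that were raised. For more reads in strong peaks that share cannot decide, since intergenic peaks can be strong too. With peaks cut into 5 groups by mean level, the raised share went from 14.8% in the weakest group to 44.1% in the strongest. Another mix of cell types within the gate stays open. Over all peaks no list of stem or mature cells differed from other peaks in camera (smallest adjusted p = 0.281), but a shift between similar cells would leave that value unchanged. The HSC list passed upward with promoter peaks only, which camera set against peaks of all classes. Promoter peaks rose as a class (39.8% raised, 15% lowered), so that pass does not bear on the mix of cells.

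The second pattern was the crowding of calls on the chromosome of the targeted gene in Idh1 R132H and Idh2 R140Q. Genome-wide action of the mutant enzyme alone as the cause of this crowding was argued against, since the share of calls there exceeded the share of tested peaks at least 10.3 times in the main fit. That value restates the crowding that defined the pattern, so it is no separate evidence. For Idh1 R132H the share on chromosome 1 (70.6%, against 6.87% of tested peaks) was 66.7% with DESeq2, 58.1% with limma voom and 55.8% with the Xist covariate. It was 35.4% with the replicate block and 30.7% with only the genotypes compared, so for calls elsewhere genome-wide action stays open. Of the 16 Idh2 R140Q calls on chromosome 7, 13 were called the same way in Idh2 R172K and 0 in Idh1 R132H, which is consistent with DNA of another strain, or the targeting itself, around an allele of the same gene. Because Idh2 R172K changed 53% of all peaks, part of that sharing may come from its own change, and no sequence variants were analysed here.

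The third pattern was the lower Vav1 signal in Tet2 knockout, whose label names no Cre. At all 3 lowered Vav1 peaks the highest Tet2 knockout library lay below the lowest of the other 16, and reads of the Vav-Cre transgene in the other genotypes may account for it. The chance share of such an order, 0.0206%, holds for a peak not picked by its values, and these 3 were picked for being lowered. The lower signal of Idh2 R172K at 1 of the 3 peaks is not given by that explanation, and loss of Tet2 and absence of the transgene cannot be told apart because the design has no Tet2 knockout with Vav-Cre, there or at the 3841 peaks called away from Vav1. The other order of Xist-high and Xist-low pools in Tet2 knockout stays open: 99.9% of the calls remained with the Xist signal as a covariate, but WT and Tet2 knockout have 2 Xist-high libraries each, which fixes that outcome, and 35% of the calls remained in the Xist-low and 40.1% in the Xist-high libraries, with fewer samples.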

How the results depend on the processing

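Counts of calls over the whole chromosome of a targeted gene were chosen after seeing the data, while those within 10 Mb were set before. The direct test of Idh2 R172K against Tet2 knockout was not among the contrasts fixed before. Following Tet2 knockout calls into the Idh genotypes was not fixed before either. Also chosen after were the Xist covariate, the Xist-low and Xist-high sets, the fits without targeted chromosomes and the summing of Tet2 knockout replicates 3 and 4. That sum gave 2793 calls for Tet2 knockout (72.1% of calls kept) and 9579 for the mean Idh genotypes against Tet2 knockout (74.3% kept). For 422 results on named peaks, the alternatives gave 4933 values of the same call, 192 weaker, 17 stronger and 0 reversed. Direction was compared only for peaks called in the main fit. A peak not called there counted as the same if it stayed uncalled, whatever its direction. Of named called peaks, 9 of 20 lost the call in at least 1 setting in Idh1 R132H, 7 of 14 in Idh2 R140Q, 8 of 104 in Idh2 R172K and 17 of 68 in Tet2 knockout. The cause was not tested except where fewer libraries, reads or peaks, or a stricter threshold, show it by construction. At an adjusted p of 0.01, Idh1 R132H against WT had 16 calls, Tet2 knockout against WT 1542, and the mean Idh genotypes against Tet2 knockout 6543. Thinned to the smallest library they had 18, 1457 and 6365, and Idh2 R140Q had 12, so depth limits these counts. The replicate block gave 96 for Idh1 R132H, 36 for Idh2 R140Q, 6634 for Tet2 knockout and 114 for Idh1 R132H against Idh2 R140Q. It moved the other counts by under 1.5 times, to 68461 for Idh2 R172K, 65205 and 61764 for Idh1 R132H and Idh2 R140Q against Idh2 R172K and 16543 for the mean Idh genotypes against Tet2 knockout, with 99.5% of the Idh2 R172K calls kept, and changed the call of no list. The Xist covariate gave 52 for Idh1 R132H. Xist-high libraries gave 6 for Idh1 R132H, 42975 for Idh2 R172K, 21 for Idh1 R132H against Idh2 R140Q, 37665 for Idh1 R132H against Idh2 R172K and 33972 for Idh2 R140Q against Idh2 R172K, and Xist-low ones 50 for Idh2 R140Q. Without the targeted chromosomes Idh1 R132H, Idh2 R140Q and their difference had 0 calls each. Fitting only the genotypes compared gave 88 for Idh1 R132H, and limma voom 77 for Idh1 R132H against Idh2 R140Q. Library size scaling moved the raised share of the mean Idh genotypes against Tet2 knockout from 29.2% (3730 and 9053) to 18.8% (2532 and 10955).

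Leaving out 1 library gave, as lowest and highest, 18 and 29 calls for Idh1 R132H, 12 and 94 for Idh2 R140Q, 58401 and 63963 for Idh2 R172K, 2116 and 4317 for Tet2 knockout, 40 and 570 for Idh1 R132H against Idh2 R140Q, 54402 and 59862 for Idh1 R132H against Idh2 R172K, 50868 and 56556 for Idh2 R140Q against Idh2 R172K, and 8373 and 13046 for the mean Idh genotypes against Tet2 knockout. Peaks shared in direction by Idh2 R172K and Tet2 knockout numbered 1927 to 3298 without 1 WT library (no other library was left out for this number), and 1318 at an adjusted p of 0.01, 5437 with the replicate block, 1220 thinned and 2112 in Xist-high libraries. Lists past the threshold numbered 0 to 0 for Idh1 R132H, 0 to 1 for Idh2 R140Q, 0 to 0 for Idh2 R172K and 1 to 2 for Tet2 knockout. With fry they were 9 for Idh2 R172K and 6 for Tet2 knockout, with promoter peaks only 1 for Idh1 R132H, 3 for Idh2 R172K and 0 for Tet2 knockout, with the mean per gene 1 for Idh2 R140Q and 2 for Tet2 knockout, and with an estimated correlation 0 for Tet2 knockout. The setting with promoter peaks only set a list's promoters against peaks of all classes. The myeloid list in Tet2 knockout had adjusted p = 0.561 with an estimated correlation and 0.0745 with promoter peaks only (0.000306 to 0.0369 leaving out 1 library).

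Correlations of fold changes with split WT libraries were -0.0364 for Idh1 R132H and Idh2 R140Q, 0.135 for Idh1 R132H and Idh2 R172K, -0.0377 for Idh1 R132H and Tet2 knockout, 0.214 for Idh2 R140Q and Idh2 R172K, 0.155 for Idh2 R140Q and Tet2 knockout and 0.389 for Idh2 R172K and Tet2 knockout. Sharing no control removes common chance values, and resting on 2 WT libraries per comparison adds noise. The parts of these in the lower values were not told apart. Over peaks called in either genotype the correlations were 0.0802 for Idh1 R132H and Idh2 R140Q, and with Tet2 knockout 0.45 for Idh1 R132H, 0.718 for Idh2 R140Q and 0.606 for Idh2 R172K, the last 0.436 in Xist-low libraries. In the order of the split values, leaving out 1 library gave 0.296 to 0.519, 0.253 to 0.36, 0.226 to 0.377, 0.299 to 0.441, 0.436 to 0.619 and 0.51 to 0.562. The promoter odds ratio of raised Idh2 R172K peaks turned to 0.737 with cyclic loess scaling. The odds ratio for Tet2 knockout calls lying near Tet2 was 1.31 within 10 Mb (adjusted p = 0.172) and 1.22 over its chromosome (adjusted p = 0.00896). Motif tests, the whole-peak alternative, the GC correction and the GC correction with the replicate block were not run.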

Other observations

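The test of other splits for Idh1 R132H against WT was chosen only after the result was seen, and the other 7 were set before. Peaks called in Tet2 knockout were followed into the Idh genotypes, which share the WT libraries with it, so some agreement arises with no effect. How much was not computed. The 2871 lowered peaks had a median log2 fold change of -1.54 in Idh2 R172K, where 89.7% were called lowered and 1.71% raised. Their median was -0.267 in Idh2 R140Q, with 5.99% above 0, and -0.117 in Idh1 R132H, with 25.6% above 0. The 973 raised peaks had medians of 0.553 in Idh2 R172K (65.4% called raised, 8.22% lowered), 0.212 in Idh2 R140Q (93.8% above 0) and 0.104 in Idh1 R132H (75.6% above 0). Jarid2 held 14.6 ± 1.84 CPM in WT, 15.1 ± 1.01 in Idh2 R140Q, 3 ± 0.731 in Idh2 R172K and 6.48 ± 0.262 in Tet2 knockout (SD, n = 4 each), and Drosha 4.34 ± 0.384, 2.98 ± 0.782, 0.512 ± 0.114 and 1.35 ± 0.199.

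Chance was tested as an explanation of each count by splitting the same libraries in other ways, in fits of only the genotypes compared. For Idh2 R172K the real split gave 65180 peaks, the highest other split 39, and 1 of 35 splits, the real one, was as large. For Tet2 knockout the real split gave 4801 peaks, 1 of 35 as large, and the highest other, which did not follow Xist, gave 1562. For Idh1 R132H against Idh2 R172K (62149 peaks, 1 of 35, highest other 47), Idh2 R140Q against Idh2 R172K (53944, 1 of 35, 48) and the mean of the Idh genotypes against Tet2 knockout (12267, 1 of 25, 0) no other split tried was as large. For the last, the other splits were random draws and not all possible ones. Splits that mix Idh2 R172K libraries into different groups also widen the spread within groups, which lowers their counts. Such low counts therefore do not show what unchanged groups would give. For Idh1 R132H the real split gave 88 and 2 of 35 were as large: the split that follows Xist gave 1176, and the next 6. For Idh2 R140Q the real split gave 14 and 4 of 35 were as large, with 2856 for a split that did not follow Xist. For Idh1 R132H against Idh2 R140Q the real split gave 48 and 3 of 35 were as large, with 5553 for a split that did not follow Xist. Splits calling several times the real count point to a structure of the samples other than genotype. Where replicate numbers pair the libraries, the 7 other splits parting all 4 pairs gave at most 2 calls for Idh1 R132H and 2 for Idh2 R140Q. So few splits cannot give a share under 0.05, so they cannot tell the real counts from chance. Over all 35 splits, 2 and 4 were as large in these comparisons, and chance was not excluded for either.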
